A study of Mus musculus with 2 samples.

How the data were processed

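The files were per-library outputs of a DNase I hypersensitivity assay (DNase-seq) on thymus from 2 female B6CASTF1/J mice aged 25 days, 1 library per animal and 1 group in all. Replicate numbers are the biological replicate numbers of the labels. Positions are on the mouse build mm10, per the labels, and none was converted. The deposited notes beside the files state that peaks and cut rates came from each library's own filtered alignment, so nothing was pooled. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here.

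Each library had 2 deposited peak lists, whose value per peak is a signal density made by the authors. The scaling of that signal is not stated. Its values were whole multiples of 1 step per library to within 0.1 of a step in 100% of peaks. The deposited false discovery rate file gives a q-value per run of bases and lists only values below 0.05. In both libraries, every peak of the longer list touched a base with a false discovery rate below 0.05, and every peak of the shorter list touched one of at most 0.001. The longer list was the main list. The deposited footprints carried the same number in every line, so only their positions were used. Because the density is the authors' own value per peak with an unstated scaling, it was used mainly to rank and describe peaks within a list. Between the libraries it was used for correlations and for the relative totals given by the steps. Ratios of density between the libraries appear only in the closing section, with that limit.

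Gene models were the protein-coding genes of GENCODE release M21 on GRCm38, the same build as mm10; chromosome lengths matched. Of 289 symbols in the gene lists, 288 were found, and Ahsp was not. Promoters were the 1 kb on either side of the gene's 5 prime end. A gene territory was the gene body with 10 kb on each side. A peak was assigned to promoter, exon, intron or intergenic DNA, in that order, by its midpoint. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

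Overlap between libraries needed at least 1 bp. It was set beside 100 seeded circular shifts of the peaks along each chromosome, which can also land in assembly gaps. Promoter peaks of each list were tested against all other protein-coding genes by a two-sided Fisher exact test. Mean peaks per territory were compared with 10000 random lists of the same size matched on decile of territory length, drawn without repeats within a decile, which is a two-sided permutation of list membership. Footprints inside peaks with a motif midpoint were compared by a two-sided Fisher exact test with 1 seeded repositioning of the same footprints within the same peaks. All p-values were adjusted by the Benjamini-Hochberg method over the 17 lists or the 32 motifs of 1 library. A list or motif was called only when its adjusted p was below 0.05 in both libraries in the same direction. Motifs were matched as consensus sequences on both strands. For CTCF in replicate 1 the p-value was too small for the software to represent and is not printed. No test compared the libraries as conditions, because they form 1 group with n = 2.

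Gene lists, motifs, tests and the rule for named genes were fixed before the data were examined, except for how random lists were drawn in the territory test. They were first drawn with repeats from genes outside the list, and the draw was changed after results had been seen. With the first draw the same 5 lists were called higher and 1 lower, and the mature and regulatory T list kept its call with the denser 50% of peaks and with the shorter deposited list. The rule named the 2 genes of each list with the most territory peaks summed over both libraries and the 2 with the fewest, with 4 and 2 for the T-lineage lists and the recombination list. In that sum the longer list of replicate 1 weighs more. Equal counts were common at these places, and such genes were ordered by their densest peak and then by symbol. It added the 5 genes with the most peaks in the lower library and the 5 densest peaks by mean rank. Some genes that this rule names are not reported here. Read depth is not stated, so intervals on shares are 95% Wilson intervals over peaks or genes and cover counting error only. The interval on the CTCF difference comes from 200 bootstrap draws of the peaks with a match, with the median of the other peaks held fixed, and it too leaves out the spread between animals.

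The code was tested on simulated data. Overlap counts differed from bedtools 2.31.1 at 0 peaks. Of 200 simulated unchanged lists, 5.0% passed an unadjusted 0.05 in the promoter test and 6.5% in the territory test. Lists raised 3-fold in peaks per territory passed in 95% of 200 cases. These simulations gave promoter peaks and territory counts to genes at random. They therefore do not cover the link of counts to gene length or peaks shared by neighbouring genes, and the error rates may differ in the real data. A motif planted in random sequence was recovered, with 0 of 31 other motifs called.

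Alternatives were 50% reciprocal overlap, equal list lengths, the densest part of each list, autosomes alone, promoter windows of 500 bp and 2 kb, any transcript start, flanks of 50 kb or none, peaks away from promoters, extended footprints and single libraries. The shorter deposited list, the exclusion of gene models over 1 Mb and the first draw of random lists as an alternative were chosen after seeing the data.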

Results

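DNase I hypersensitive sites were mapped in thymus from 2 female B6CASTF1/J mice aged 25 days. This strain is the first-generation cross of C57BL/6J and CAST mice. DNase I cuts DNA where chromatin is accessible, so dense cutting marks promoters, enhancers and other regulatory DNA. Short protected stretches inside such sites (footprints) can mark bound protein, though binding itself was not tested here. The thymus is the organ in which T cells develop. Both libraries belonged to 1 group, each from its own animal, and no condition was contrasted. The comparisons were the agreement between the animals and comparisons of genes, regions and sequence motifs within each library. Tests over genes or footprints describe these 2 libraries, since genes and footprints are not replicates.

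Peaks numbered 127552 in replicate 1 and 67270 in replicate 2, with summed lengths of 24.8 and 13.2 Mb. Some peaks overlapped, and the DNA they covered was 24.5 and 13.1 Mb. The mean was 97411 ± 42626 peaks and 19.03 ± 8.20 Mb of summed length (SD, n = 2), so replicate 1 held 1.90 times as many peaks as replicate 2. The median peak width was 180 bp in replicate 1 and 200 bp in replicate 2. Footprints numbered 363775 in replicate 1 and 203939 in replicate 2, with median widths of 11 and 10 bp. Read totals are not stated in the sources used here. The deposited peak densities were whole multiples of 0.00529 in replicate 1 and 0.0060 in replicate 2, which gives relative totals of 1.13 if each density was divided by its library's total.

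The densest sites were shared between the animals, and the weakest sites of either library were mostly not. By at least 1 bp, 88.8% of replicate 2 peaks (95% Wilson interval 88.5% to 89.0%) overlapped a replicate 1 peak, and 46.9% of replicate 1 peaks (46.6% to 47.2%) overlapped a replicate 2 peak. After random circular shifts along each chromosome the mean shares were 1.94% and 1.03%, and none of 100 shifts exceeded 2.20% and 1.15%. In the densest decile of each list, 98.8% of replicate 1 peaks and 99.9% of replicate 2 peaks had a partner. In the least dense decile the shares were 4.95% and 24.6%. Replicate 1 peaks with a partner had a median density of 2.26 and those without one 0.439. Across 59843 pairs of overlapping peaks, densities correlated with a Spearman rho of 0.811 and a Pearson r of 0.844 on the log10 scale. These correlations are across peaks, which are not independent replicates. With the longer list reduced to the length of the shorter by density, 75.8% of the peaks of either library had a partner.

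**Figure D1:**
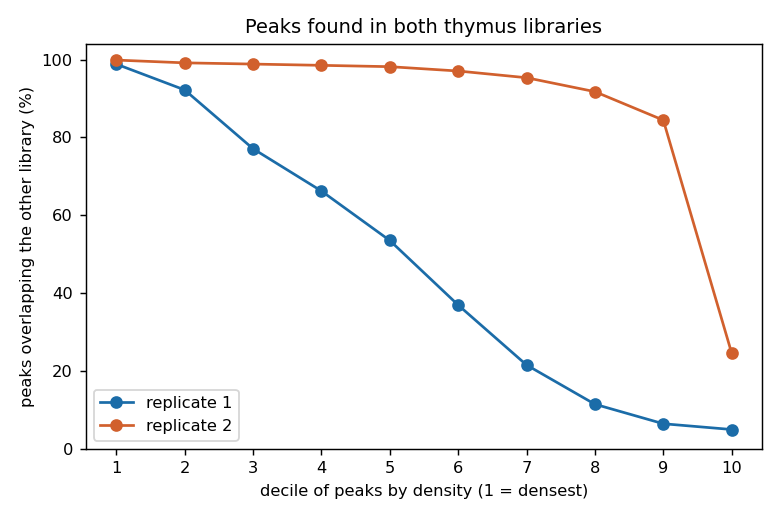
Share of peaks (%, vertical axis) that overlap a peak of the other library, by decile of peak density within each list (horizontal axis, 1 is densest); points are single libraries. Sharing falls from 98.8% to 4.95% in replicate 1 and stays at 84.4% or more in replicate 2 until the last decile, at 24.6%.

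Promoters were the most over-represented class of accessible sites. Peaks centred within 1 kb of the start of a protein-coding gene made up 18.7% of peaks in replicate 1 (95% Wilson interval 18.5% to 18.9%) and 26.1% in replicate 2 (25.8% to 26.5%), with a mean of 22.4% ± 5.27 (SD, n = 2). These shares were 11.3 and 15.8 times those after circular shifts. Exons outside promoters held 7.03% ± 0.144 of peaks, introns 35.8% ± 3.59 and intergenic DNA 34.8% ± 1.83 (SD, n = 2). Intergenic peaks were under-represented, at 0.614 and 0.569 times the shifted share. Promoter peaks were also denser, with medians of 2.34 against 0.719 elsewhere in replicate 1 and 2.55 against 0.774 in replicate 2.

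Promoters of T-lineage genes were open in nearly every case, and those of liver, erythroid and muscle genes were mostly closed. Of 21938 protein-coding genes, 61.7% in replicate 1 and 55.1% in replicate 2 had a peak within 1 kb of the gene start. Of 25 T-lineage genes, which include the T-cell receptor complex and its signalling partners, 24 had such a peak in replicate 1 and 22 in replicate 2 (Fisher exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00067 and 0.00364). Of 25 T-lineage transcription factors, 25 and 23 were open (Fisher exact adjusted p = 0.000157 and 0.000799). The list of V(D)J recombination genes, whose products cut and rejoin the antigen receptor genes, had 14 of 15 open in both libraries (Fisher exact adjusted p = 0.0292 and 0.00595). Genes of thymocyte selection and apoptosis were open in 16 of 16 and 15 of 16 cases, cell cycle genes in 16 of 16 in both, and housekeeping genes in 16 of 16 and 15 of 16. Fisher exact adjusted p-values for these 3 lists lay between 0.000799 and 0.00441. Cell cycle and housekeeping genes were open to a like degree. Promoter peaks therefore do not set the T-lineage, recombination or selection lists apart from broadly used genes.

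Liver genes had a promoter peak in 2 of 16 cases in replicate 1 and 0 of 16 in replicate 2 (Fisher exact adjusted p = 0.000621 and 4.6e-05). Erythroid genes were open in 3 and 2 of 14 cases (Fisher exact adjusted p = 0.00915 and 0.00568), and muscle genes in 5 and 3 of 16 (Fisher exact adjusted p = 0.0344 and 0.00762). With any annotated transcript start counted, the erythroid and muscle lists no longer passed in both libraries. In replicate 2 alone, 5 lists were lower, with the myeloid and dendritic and the adipocyte and parathyroid lists added. The other 8 of 17 lists did not pass in both libraries. Among them, mature and regulatory T cell genes were open in 12 and 10 of 14 cases and thymic epithelium genes in 10 and 8 of 20. B cell genes were open in 9 and 8 of 16 cases, and myeloid and dendritic genes in 7 and 5 of 18. NK and innate-like genes were open in 11 of 15 in both libraries, and neuron genes in 10 and 6 of 16. Stroma and endothelium genes were open in 7 and 6 of 17 cases, and adipocyte and parathyroid genes in 4 and 2 of 13.

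**Figure D2:**
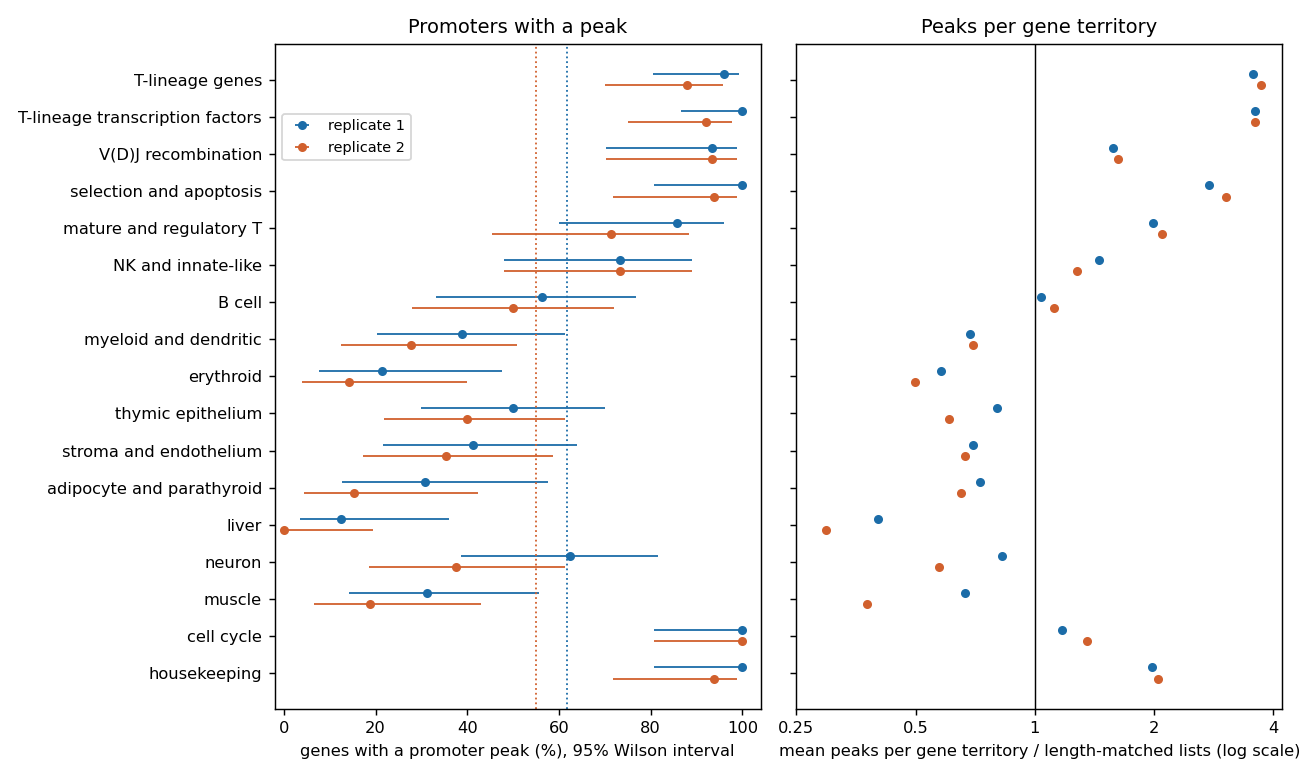
Left, genes of each list with a promoter peak (%, with 95% Wilson intervals); dotted lines mark all protein-coding genes, at 61.7% in replicate 1 and 55.1% in replicate 2. Right, mean peaks per gene territory divided by the mean of length-matched random lists (log scale); T-lineage genes lie at 3.56 and 3.72 and liver genes at 0.402 and 0.297.

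Counting every peak in the gene body and 10 kb on each side, T-lineage genes were surrounded by far more accessible sites than other genes of like length. T-lineage genes held a mean of 20.7 peaks in replicate 1 and 12.4 in replicate 2, which was 3.56 and 3.72 times the mean of length-matched random lists (two-sided permutation of list membership, Benjamini-Hochberg adjusted p = 0.0153 and 0.0136). T-lineage transcription factors held 29.1 and 15.5 peaks, 3.60 times the matched mean in both libraries (permutation adjusted p = 0.0197 and 0.0195). Selection and apoptosis genes were at 2.75 and 3.04 times (permutation adjusted p = 0.0153 and 0.0136). Mature and regulatory T cell genes were at 1.99 and 2.10 times (permutation adjusted p = 0.0232 and 0.0209), and housekeeping genes at 1.97 and 2.05 times (permutation adjusted p = 0.0153 and 0.0198). Liver genes were at 0.402 and 0.297 times (permutation adjusted p = 0.0153 and 0.0136). The mature and regulatory T list lost its call with the gene body alone, with 50 kb on each side, with the denser 50% of peaks and with the shorter deposited list. The housekeeping and liver lists lost theirs when peaks within 1 kb of a gene start were left out. Neighbouring members of a list, such as Cd3d, Cd3e and Cd3g, have overlapping territories, so 1 peak can count more than once. The random lists were not matched on this.

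The remaining 11 lists did not pass in both libraries. V(D)J recombination genes were at 1.57 and 1.62 times the matched mean, NK and innate-like genes at 1.45 and 1.28, cell cycle genes at 1.17 and 1.35 and B cell genes at 1.04 and 1.12. Ratios below 1 were found for myeloid and dendritic genes (0.686 and 0.700), erythroid genes (0.579 and 0.498), thymic epithelium (0.804 and 0.607) and stroma and endothelium (0.699 and 0.666). The same held for adipocyte and parathyroid genes (0.729 and 0.651), neuron genes (0.826 and 0.573) and muscle genes (0.664 and 0.378).

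Among T-lineage genes, Cd8b1 (ENSMUSG00000053044), which encodes a chain of the CD8 co-receptor, had the highest mean count, 43.5 ± 14.8 peaks (SD, n = 2), with 54 in replicate 1 and 33 in replicate 2. It lies on chromosome 6 from 71322788 to 71337494. Cd247, the zeta chain of the T-cell receptor complex, had 40.0 ± 8.49 peaks on chromosome 1 from 165788681 to 165877277, and had 34 in replicate 1 and 46 in replicate 2, where it had the most of this list. Rhoh had 22.5 ± 7.78 peaks. The fewest were at Cd5 (8.0 ± 2.83) and Trat1 (4.5 ± 2.12), and Trat1 had a promoter peak in replicate 1 alone.

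Tcf7 (ENSMUSG00000000782), the gene of the T-cell factor TCF-1, led the transcription factors with 51.0 ± 12.7 peaks (SD, n = 2) on chromosome 11 from 52252371 to 52283014. Runx1 had 47.5 ± 17.7 peaks. Ets1 and Satb1 differed widely between the animals, with 60 and 15 peaks at Ets1 and 60 and 14 at Satb1 in replicates 1 and 2. Cbfb, the shared partner of RUNX proteins, had 4 peaks in each library and Heyl 3.5 ± 3.54. In the recombination list, Hmgb1 had 32.0 ± 9.90 peaks and Dntt, which encodes terminal deoxynucleotidyl transferase, 24.5 ± 0.707. Rag2, a subunit of the recombinase, had 30 peaks in replicate 1 and 5 in replicate 2. Xrcc6 had 17.0 ± 5.66 peaks and no promoter peak at the annotated gene start. Prkdc had 3.0 ± 1.41 and Polm 2.5 ± 2.12.

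Bcl2l1 (26.0 ± 14.1 peaks) and Bcl2l11 (18.0 ± 4.24), which encode the survival protein BCL-XL and the death-promoting protein BIM, led the selection list, with Egr3 (4.5 ± 2.12) at its end, after Cd69 and Bax, which tied at 5.5 ± 0.707. Il2ra (19.5 ± 10.6) and Ccr7 (15 ± 8.49) led the mature and regulatory T list, with Icos (2 in each library) at its end and Il7r (4.0 ± 1.41) near it. Zbtb16, the gene of the innate-like lineage factor PLZF, had 21 ± 4.24 peaks and Id2 10.5 ± 6.36, while Gzmb and Ncr1 had none in either library. Aurkb (12 ± 1.41) led the cell cycle genes, followed by Mcm2 (8.0 ± 1.41) and E2f1 (8 in each library), where Plk1 had 2.0 ± 1.41 and Mcm3 1.5 ± 0.707. Tubb5 (12.5 ± 3.54) led the housekeeping genes, followed by Actb and Ywhaz, which tied at 10.5 ± 2.12, where Rps3 had 3.5 ± 0.707 and Sdha 2.5 ± 0.707. All errors are SD over n = 2.

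Lists of other cell types each held some genes with several peaks. Ebf1 had 14.5 ± 6.36 and Cd79a 9.5 ± 2.12 peaks in the B cell list, against 0.5 ± 0.707 at Ms4a1 and 1.5 ± 2.12 at Fcrla. Itgam had 10 ± 4.24 and Spi1 7.5 ± 0.707 in the myeloid list, and Ly6g had none and Adgre1 0.5 ± 0.707. In the erythroid list Klf1 had 6.5 ± 3.54 and Ank1 6.5 ± 4.95, with none at Hbb-bs. Prss16 (8.5 ± 3.54) and Ly75 (7.5 ± 3.54) led the thymic epithelium list, with 0.5 ± 0.707 at Tbata and none at Cldn3. Pecam1 (17.5 ± 3.54) and Vwf (7.5 ± 3.54) led stroma and endothelium, with none at Dcn and Tek. Lipe (9.5 ± 6.36) and Plin1 (6.0 ± 1.41) led the adipocyte and parathyroid list, with 1.0 ± 1.41 at Casr and none at Lep. Hnf4a had 5.0 ± 2.83 in the liver list, where Tdo2 and Ttr had none. Rbfox3 had 20 ± 18.4 and Camk2a 17.0 ± 7.07 in the neuron list, with 0.5 ± 0.707 at Stmn2 and Neurod6. Actn2 had 8.0 ± 4.24 and Ckm 6.5 ± 2.12 in the muscle list, with 0.5 ± 0.707 at Acta1 and Myh4. Among these leading genes, Cd79a, Klf1, Prss16, Vwf, Lipe, Plin1, Hnf4a and Rbfox3 had no promoter peak in either library. Ank1 had a promoter peak in replicate 1 alone. Ebf1, Itgam, Spi1, Ly75, Pecam1, Camk2a, Actn2 and Ckm had a promoter peak in both. A territory can also take in sites of neighbouring genes. All errors are SD over n = 2.

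Over all protein-coding genes, the most peaks fell in long or composite gene models. Gm20388, a model of 4.43 Mb on chromosome 8, held 684 and 386 peaks in replicates 1 and 2, and Fgfr2, annotated over 2.96 Mb, held 204 and 119. Gse1 held 129 and 75, Gm20696 97 and 66, and Foxp1, which encodes a forkhead factor of lymphocytes, 93 and 61. Gse1 lies within the span of Gm20388, and Gm20696 overlaps Foxp1, so these counts share peaks.

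The 5 densest peaks by mean rank were near 3 genes. Of these, 3 lay at the end of chromosome X in or near Gm21887, at 169997961 to 169998220, 169991161 to 169991420 and 170009861 to 170010160. Their deposited densities in replicate 1 were 164.9, 108.5 and 104.9. The 31-base words of these 3 peaks had medians of 6, 4 and 4 copies in the genome, some on other chromosomes, so these sequences were not unique in the genome. The peak at the Dynlt1b promoter on chromosome 17 (6430021 to 6430180, density 151.6) had a median of 2 copies. The promoter peak of Dnpep on chromosome 1 (75317481 to 75317940, density 71.7) had a median of 1.

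Footprints were shared between the animals more often than random placement within their peaks would give. Of replicate 2 footprints 67.9% (95% Wilson interval 67.7% to 68.1%) overlapped a replicate 1 footprint, and of replicate 1 footprints 35.7% (35.6% to 35.9%) overlapped one of replicate 2. Inside peaks shared by both libraries the shares were 69.6% and 54.8%, against 47.7% and 39.5% when footprints were moved at random within their peaks. The highest of 100 such repositionings gave 48.0% and 39.7%. These moves were even along each peak. They do not account for footprints of both libraries favouring the same part of a peak.

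Motifs were compared in the 280221 and 160927 footprints inside peaks, which leaves out 83554 in replicate 1 and 43012 in replicate 2. Of 32 motifs, 13 were found in more footprints than in repositioned footprints in both libraries and 8 in fewer (two-sided Fisher exact test, Benjamini-Hochberg adjusted). Repositioned footprints were placed evenly at random along their peaks. Distance from the peak centre and local base composition were therefore not matched. CTCF, the insulator protein that anchors chromatin loops, matched CCASYAGRKGGC in 2.24% of these footprints in replicate 1 against 0.95% when repositioned, and in 1.57% against 0.440% in replicate 2 (Fisher exact adjusted p = 3.3e-238 in replicate 2). The TCF/LEF motif CTTTGAWS was 1.81 and 2.42 times as frequent as in repositioned footprints (Fisher exact adjusted p = 7.6e-45 and 1.5e-71). RUNX was 1.196 and 1.45 times as frequent (Fisher exact adjusted p = 4.1e-13 and 6.9e-31), and ETS 1.75 and 1.87 times (Fisher exact adjusted p = 1.5e-27 and 6.8e-31). NRF1 reached 2.24 and 2.53 times, SP/KLF 2.24 and 2.32, CRE 2.06 and 2.60, and EGR 2.08 and 2.47. NFY (0.95 and 1.04) and YY1 (1.04 and 1.16), which were also more frequent in promoter peaks than in other peaks, were not called. REST reached 3.56 and 3.25 times and ZNF143 1.70 and 2.20, both on few footprints. The E-box motifs were at 1.08 and 1.07 times for CAGCTG, 1.201 and 1.13 for CACCTG and 1.33 and 1.58 for CACGTG. The density of CAGCTG in footprints was below that in the rest of the same peaks, at 0.972 and 0.942 times.

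The 8 motifs found in fewer footprints were FOXA (0.383 and 0.226 times), POU/OCT (0.588 and 0.495), AP-1 (0.707 and 0.753), the PU.1-type ETS motif (0.735 and 0.800), MYB (0.807 and 0.743), SOX (0.773 and 0.738), MEF2 (0.786 and 0.687) and TEAD (0.739 and 0.837). With footprints extended by 5 bp on each side, 3 of 32 motifs were called lower, and TEAD turned to 1.03 times the repositioned share and was not called. The remaining 11 motifs were not called in both libraries, among them GATA (0.676 and 0.862), ROR (0.777 and 0.696) and IKZF (1.04 and 1.35). Reversing the bases of a motif keeps base composition but not the pairs of neighbouring bases. Against this control CTCF had 6283 matches in replicate 1 footprints per reversed match, TCF/LEF 5.14 and RUNX 1.87. The CTCF value rests on 1 reversed match. NF-kB, which was not called, had ratios below 1 in both libraries. So did FOXA and MYB among the motifs found in fewer footprints. The other motifs found in fewer footprints had ratios above 1 in both, so there the controls did not point the same way. POU/OCT was at 9.09 and 9.6, and the PU.1-type ETS motif at 3.58 and 5.22. The reversed forms of SP/KLF and EGR match the same sites, so that control does not apply to them.

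**Figure D3:**
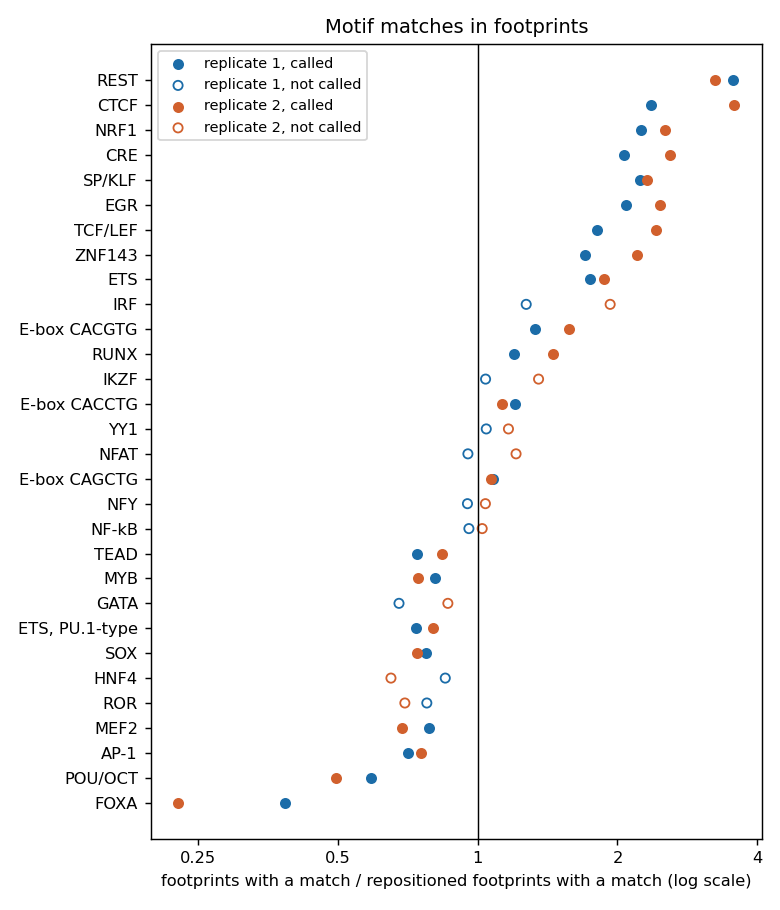
Footprints inside peaks with a motif match divided by repositioned footprints with a match (log scale), for each motif with matches in both sets; filled points are motifs called in both libraries in the same direction. CTCF lies at 2.36 in replicate 1 and 3.57 in replicate 2, and FOXA at 0.383 and 0.226.

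Accessible sites were sparse on the X chromosome. It held 19.2 peaks per Mb in replicate 1 and 10.6 in replicate 2, against autosome medians of 48.2 and 26.2, a ratio of 0.402 ± 0.00483 (SD, n = 2). Autosomes ranged from 38.5 to 80.0 per Mb in replicate 1 and from 19.8 to 42.8 in replicate 2, with the highest value on chromosome 11 in both. Per protein-coding gene the X chromosome had 3.46 and 1.92 peaks against autosome medians of 6.14 and 3.18. The Y chromosome held 41 peaks in replicate 1 and 50 in replicate 2, which is 0.447 and 0.545 per Mb, in animals labelled female.

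**Figure D4:**
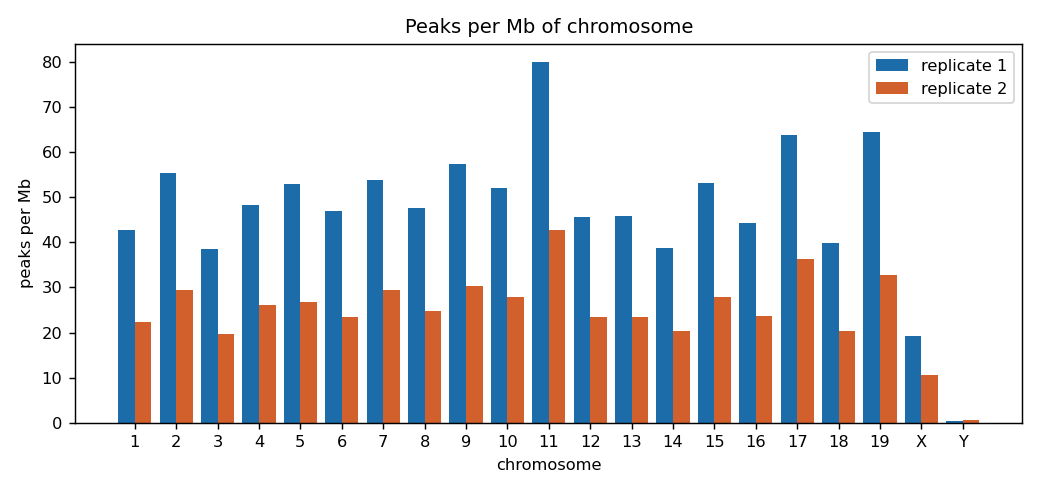
Peaks per Mb (vertical axis) on each chromosome (horizontal axis); bars are single libraries. The X chromosome, at 19.2 and 10.6 peaks per Mb, lies below every autosome in both libraries.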

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

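The shorter deposited list, footprints within it, the exclusion of gene models over 1 Mb and random lists drawn with repeats were chosen after seeing the data. The 6 lists called higher by promoter peaks numbered 6 under all alternatives run, and the 5 called higher by territory peaks numbered 4 or 5. The cause was not tested for the changes below unless the alternative's construction shows it.

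Keeping the densest 50% of each list, by construction, gave a mean of 48706 peaks and 10.6 Mb. In that setting 52.0% of replicate 1 peaks and 98.1% of replicate 2 peaks were shared, the Spearman correlation was 0.785, the promoter share 32.1% and the X to autosome ratio 0.313. With 50% reciprocal overlap the shared peaks were 40.8% and 77.4%, the shared footprints 25.3% and 45.0%, and the correlation 0.797. With the longer peak list reduced by density both peak shares were 75.8%. With the longer footprint list thinned at random, which lowers the share by construction, 38.6% of replicate 2 footprints were shared. On autosomes alone 89.2% of replicate 2 peaks were shared. The shorter deposited list gave shares of 49.0% and 92.4%, a correlation of 0.800 and an X ratio of 0.352, and its footprints were shared in 33.8% and 64.9% of cases. A 500 bp promoter window, narrower by construction, gave a promoter share of 16.2%. The X ratio per protein-coding gene was 0.583.

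Lists called lower by promoter peaks numbered 1 with any transcript start, and 5 with the densest 50% of peaks, with equal list lengths and with the shorter deposited list. Lists called lower by territory peaks numbered 0 with peaks over 1 kb from a gene start. Motifs called lower in footprints numbered 3 with extended footprints. In that setting NF-kB turned to 1.22 times the repositioned share and was called, and TEAD turned to 1.03 times and was not called.

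Single libraries ranged from 67270 to 127552 peaks, from 13.2 to 24.8 Mb and from 18.7% to 26.1% in promoters. Lists called lower ranged from 3 to 5 by promoters and from 1 to 2 by territory, in each case with the higher number in replicate 2 alone. Without 1 library no overlap or correlation exists. The densest part of the footprint lists was not run, because their deposited number does not vary. Of the least dense decile of replicate 1, 4.95% had a partner; read totals are not stated, so the part of depth in this is open.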

Other observations

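The test of depth, the test of weak sites and the check of Y-linked genes were chosen after the results they measure were seen. The tests on CTCF and on shared sequence were chosen before. The value set against a scaling factor between the libraries is the CTCF difference itself, so it is not separate support for that pattern.

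The antigen receptor loci were chosen after the data were examined. Peaks were dense across the T-cell receptor alpha locus on chromosome 14, at 122.5 and 84.6 per Mb in replicates 1 and 2, and the beta locus on chromosome 6, at 112.4 and 62.9, against genome means of 46.8 and 24.7. Of 110 variable segments of the alpha locus, 70 and 62 had a peak within 1 kb, and of 22 of the beta locus, 15 and 12. These shares were 63.6% and 56.4% for alpha and 68.2% and 54.5% for beta. They were close to the 61.7% and 55.1% of protein-coding genes with a peak within 1 kb of the gene start. The immunoglobulin heavy chain locus on chromosome 12 was also accessible, at 88.5 and 44.4 per Mb. Near a peak were 81 and 48 of 113 variable and 3 and 0 of 19 diversity segments. Of its joining segments 4 and 1 of 4 were near a peak, and of its constant segments 3 and 1 of 8. The kappa light chain locus was nearly closed, at 7.88 and 2.21 per Mb, with 1 of 102 variable segments near a peak in each library. The gamma locus on chromosome 13 was near the genome mean, at 57.2 and 28.6 per Mb, with 5 and 3 of 7 variable, 0 of 4 joining and 0 of 4 constant segments near a peak. The lambda light chain locus was at 25.1 and 0 per Mb. Of the joining segments, 15 and 10 of 51 of the alpha locus and 13 and 8 of 13 of the beta locus were near a peak. The delta locus, at 104.6 and 67.2 per Mb, lies within the alpha span, so its peaks count in both. No test was run on these counts, and these loci were not checked for copies of their sequence elsewhere in the genome.

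The 10 windows of 50 kb with the most peaks in the lower library were also looked up after the data were examined. The window holding Zfp36l2 on chromosome 17 had 56 and 52 peaks in replicates 1 and 2, that of Tcf7 on chromosome 11 had 63 and 45, and that of Cd8b1 and Smyd1 on chromosome 6 had 72 and 41. A window on chromosome 4 from 3050001 to 3100000, with no protein-coding gene, had 40 and 58. The others lay at Taf8 and Ccnd3 (50 and 26), Thy1 (35 and 23), Pck1 (32 and 25), Dntt (28 and 26) and Nfic (27 and 28), and in a stretch of chromosome 15 with no protein-coding gene (51 and 29). Unlike the densest peaks, these windows were not checked for copies of their sequence elsewhere in the genome, so repeated sequence stays open for them.

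Peaks with a CTCF match differed between the animals far more than other shared peaks did, while for the other motifs with enough shared peaks to compare, REST not among them, the same log2 difference ran from -0.46 (ROR) to 0.30 (YY1). Within replicate 1, the 2945 shared peaks with a match had a median density 2.24 times that of other shared peaks, and within replicate 2 the same sites were at 0.703 times. The log2 ratio of replicate 1 to replicate 2 was 1.86 higher at CTCF matches (95% bootstrap interval over peaks 1.83 to 1.89, without the spread between animals), a difference that 1 scaling factor cannot give, whatever the unstated scaling of the densities. It was 1.98 as the median within deciles of GC content and fell from 2.24 in the lowest decile to 0.788 in the highest, so GC content does not account for all of it, and at 2.03 among peaks over 1 kb from a gene start, neither does distance from promoters. Handling of the tissue, digestion, fragment selection and a difference between the animals stay open, and no biological explanation was tested.

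Replicate 1 had 1.90 times as many peaks as replicate 2. Peaks without a partner had 0.194 times the median density of those with one in replicate 1 and 0.239 times in replicate 2. Weak sites falling below the detection limit in replicate 2 therefore cannot be told apart from weak sites being missed in either library. Sequencing depth cannot be told apart from other differences in sensitivity: shared peaks of mean density over 5 were 1.68 times as dense in replicate 1, but the scaling of the densities is not stated. Relative totals were 1.13 if each density was divided by its library's total, against 1.90 times as many peaks. That division is not stated either.

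Peaks on the Y chromosome appeared in both libraries from animals labelled female. Sequence shared with other chromosomes may give them, since 87.8% of Y peaks in replicate 1 and 92.0% in replicate 2 held a 31-base word found on another chromosome, against 19.1% of 199 and 10% of 200 random autosomal peaks with a word to test. A male animal or male tissue is argued against by the promoters of Ddx3y, Kdm5d, Uty and Eif2s3y, of which 0 had a peak in either library, though the territory of Kdm5d held 1 peak in replicate 2.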
